A study of Mus musculus with 6 samples.

How the data were processed

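RNA of RAW264.7 macrophages was sequenced from 6 libraries, 3 of the Gel/S group and 3 of the C/D group, with a SMARTER mRNA-Seq library kit per the labels' protocols. The sample titles gave each library its group and replicate number. In the deposited table the control columns carry the word GEL and the others the letters US, which were read as ultrasound and so as C/D, since the labels apply ultrasound to C/D only. The labels do not spell this out, so every direction rests on that reading.

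The authors' table lists 54532 gene entries with several kinds of value. Raw counts of reads or fragments per gene were made by the authors for each library, without normalization, per the file headers. The FPKM values, also from the authors, are counts per kilobase of the listed gene length and per scaled library total, and the total they imply differs from the sum of the counts, so a scaling that is not given in the sources used here went into them. The signal columns of the deposited table are the authors' group means of counts scaled for library size, per the file headers. The log2 fold changes in the deposited table are the authors' ratio of Gel/S over C/D, and their sign was turned for the comparison given below. The p-values and adjusted p-values of the deposited table are the authors' own, and their test and adjustment are not given in the sources used here. Reads were mapped to GRCm38 (mm10) per the submitters' processing notes. Aligner, counter, annotation release and strandedness are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and a counter that drops or splits reads with several matches changes the counts of genes with pseudogenes or close paralogs.

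Of the gene IDs, 54495 are in GENCODE M21, and 53585 of these (98.33%) have the same chromosome, start and end there, so coordinates are printed for GRCm38. No entry lacked a gene, so 0 entries were left out of the library totals. A spreadsheet had turned 27 symbols into dates, and these were restored from the gene IDs. Counts of the 100 symbols with several entries were summed. A gene was tested when its mean FPKM over the 6 libraries was at least 1, which left 11708 genes holding over 99% of the counts of each library.

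The design fixed before the data were examined planned limma on log2(FPKM + 1) and, if counts were found, edgeR. Counts were found, so the test is the edgeR 4.0.16 quasi-likelihood test on counts with TMM factors in R 4.3.3. Every adjusted p of a gene is from that test with Benjamini-Hochberg adjustment, with a threshold of 0.05, unless another tool is named. A positive log2 fold change is higher in C/D. Its standard error is the absolute log2 fold change over the square root of the F statistic. Levels are FPKM as deposited. Of 42 gene lists fixed in advance, 37 had at least 5 tested members and were compared with all other tested genes by camera (limma 3.58.1, preset correlation of 0.01) on log2 CPM (counts scaled to library size) with a prior count of 2, adjusted over these lists. Of these, 18 passed. With a correlation estimated per list, 0 lists passed camera (smallest adjusted p = 0.373), while fry, which tests whether a list's genes move one way on balance, gave 17 lists with an adjusted p under 0.05. Only 10 of the 18 camera calls are among these, and the other 8 (complex I, complexes II to IV, ATP synthase, mitochondrial mRNAs, immediate early genes, lysosome, and both ribosomal protein lists) had a fry adjusted p of 0.0602 to 0.242. The unadjusted count of changed genes, at a p under 0.05 by edgeR, was 4800.

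The genes named were fixed by a rule: the 12 highest and 12 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean FPKM of at least 2, no overlap between the groups and a symbol that is not a predicted or clone name; up to 4 members per list with the smallest adjusted p, or 2 with the smallest p where none passed; and 19 genes of macrophage and bone biology. Members named only because their list had 5 or fewer risen or fallen genes were chosen after their values were seen. Some genes that the rule takes are not reported here. After the main results were seen, 10 further lists were fixed without looking up their members' values, although some members (such as Actb, Vcl, Lpcat3 and Fosl1) were also among the main lists or named genes, and transcription factor families were taken from a column of the authors' table. Their results stand in the closing observations.

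The pipeline was tested on simulated counts drawn for the 11708 genes from the means and library sizes of C/D and Gel/S, in 3 datasets. It called 23.3% of genes changed 1.3-fold, 65.3% at 1.5-fold, 90% at 2-fold and 95.3% at 3-fold (150 genes at each fold over the datasets), and 28 of 34524 unchanged genes. The glycolysis list, shifted by 1.3-fold, was called in 3 of 3 datasets. No other list was called, leaving aside the hypoxia list, which shares genes with it and was not counted. The simulated genes varied independently, so this does not test how camera behaves when the genes of a list vary together. The common biological coefficient of variation was 10.2%. Totals ran from 12818831 to 16525699 counts per library. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 3.36 to 41.3, so all were kept as separate libraries, although repeat preparations from the same RNA are not excluded. Where a group had no counts, a floor of 3 counts over the group was used, and it covers counting error only, since reads are not independent molecules.

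The alternatives planned before the data were seen were other pseudocounts, filters, scalings (quantile, median-of-ratios, TPM), limma variants, a Welch test, DESeq2 1.42.0, the replicate number as a block, fold thresholds, unsummed symbols, other camera settings and each library left out. A length and GC correction, the edgeR expression filter, and nuclear protein-coding genes alone were added after the data were seen. The limma fit on log2(FPKM + 1), planned as the main test for a table without counts, became an alternative once counts were found. To set a list against gene length, GC content and expression, 10000 random lists were drawn, each member being replaced by 1 of its 100 nearest genes in these properties. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.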

Results

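RAW264.7 is a mouse macrophage line, derived from a virus-induced tumour, that can also be driven to form osteoclasts. The cells were cultured for 3 d in 1 of 2 ways. Gel/S cells, the control, were kept static with plain GelMA, a gelatin hydrogel modified with methacryloyl groups. C/D cells were kept with a composite of GelMA, the conducting polymer blend PEDOT:PSS and PLLA/PDA, and received ultrasound at 48 kHz for 5 min. Messenger RNA was sequenced in 3 libraries per group, with total counts of 15896779, 16525699 and 15579679 in Gel/S 1 to 3 and of 12818831, 15802627 and 14909268 in C/D 1 to 3. The series title places the work in immune-guided bone repair and mitochondrial metabolism. The design thus holds 1 comparison, C/D against Gel/S, which asks how macrophages differ between the stimulated conductive gel and the static plain gel. Material and ultrasound change together, so a difference belongs to the combination. The labels do not say that the replicates are separate cultures, so every p-value below measures only the spread between these samples, which may be technical. All means are given ± SD over n = 3 libraries.

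Macrophages of the C/D group held less mRNA for cholesterol synthesis, DNA replication, glycolysis and NF-kB targets than those of Gel/S, and more mRNA for subunits of complex I, ATP synthase and the cytosolic ribosome. All 24 measured genes of cholesterol synthesis and uptake fell, with a median log2 fold change of −0.90, 22 of 27 DNA replication genes fell, and so did 15 of 23 glycolysis genes and 15 of 23 NF-kB targets. In the other direction, 21 of 36 complex I genes rose, with a median log2 fold change of 0.39, as did 9 of 18 ATP synthase genes and 18 of 53 genes of the cytosolic ribosome. These lists passed camera with its preset correlation, and none of the 37 lists tested passes with an estimated correlation (smallest adjusted p = 0.373). The rises were the less secure part. Fry called the lists that fell (fry adjusted p of 0.00319 to 0.00617) but not complex I (0.0602), ATP synthase (0.0818) or the cytosolic ribosome (0.129). Tnf, a main inflammatory cytokine of macrophages, fell from 278 ± 13.3 to 168 ± 7.69 FPKM, and Vegfa, an angiogenic growth factor, rose from 38.6 ± 2.43 to 52.9 ± 4.31 FPKM.

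Of 11708 genes tested, 1532 rose and 1631 fell in C/D at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), together 27.0% of the genes. Most changes were moderate. The median absolute log2 fold change of the changed genes was 0.49, and 153 genes rose and 61 fell by at least 2-fold. The FPKM values of the groups did not overlap for 5411 genes (46.2%), where chance gives 10%. The share of calls that rose was 48.4%, and it was 40.9% (1020 rose, 1471 fell) with limma on log2(FPKM + 1). With limma on values also rescaled to sum to the same total in each library (TPM) it was 29.5% (633 rose, 1510 fell), and the median log2 fold change of all genes was −0.12, against −0.03 in the former fit. TPM, quantile normalization and sample weights below are limma fits too, so they change the test as well. The calls also thinned when some libraries were left out, with 887 risen and 1005 fallen without Gel/S 3, 910 and 902 without C/D 1, 928 and 876 without C/D 2, and 954 and 1006 without C/D 3. The authors' deposited table, which holds their own p-values, lists 3252 genes with an adjusted p under 0.05, of which 1299 are higher and 1953 lower in C/D. Of 11698 genes in both analyses, 2756 were called in both, 2756 of them in the same direction, with 405 called only here and 347 only in the authors' deposited table.

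The libraries separated by group along the first principal component of log2 CPM (counts scaled to library size), which held 55.8% of the variance. Its scores were −34.6, −11.3 and −17.7 for Gel/S 1 to 3 and 25.6, 19.8 and 18.2 for C/D 1 to 3, so Gel/S 1 stood farthest out. Several signs of library content moved with the group. Mitochondrial transcripts took 7.34 ± 1.72% of the counts in Gel/S, lowest in Gel/S 1 at 5.59%, and 9.84 ± 0.606% in C/D (2-sided exact permutation p = 0.1, the smallest that 3 against 3 samples allow). The groups nearly met, with 9.02% in Gel/S 2 and 9.17% in C/D 1. Long intergenic non-coding RNAs took 0.580 ± 0.0286% and 0.835 ± 0.0314% (exact p = 0.1), and nuclear ribosomal RNA 0.0126 ± 0.00120% and 0.0200 ± 0.00120% (exact p = 0.1). A count was found for 18863 ± 105 genes in Gel/S and for 19386 ± 90.3 in C/D (exact p = 0.1).

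**Figure D1:**
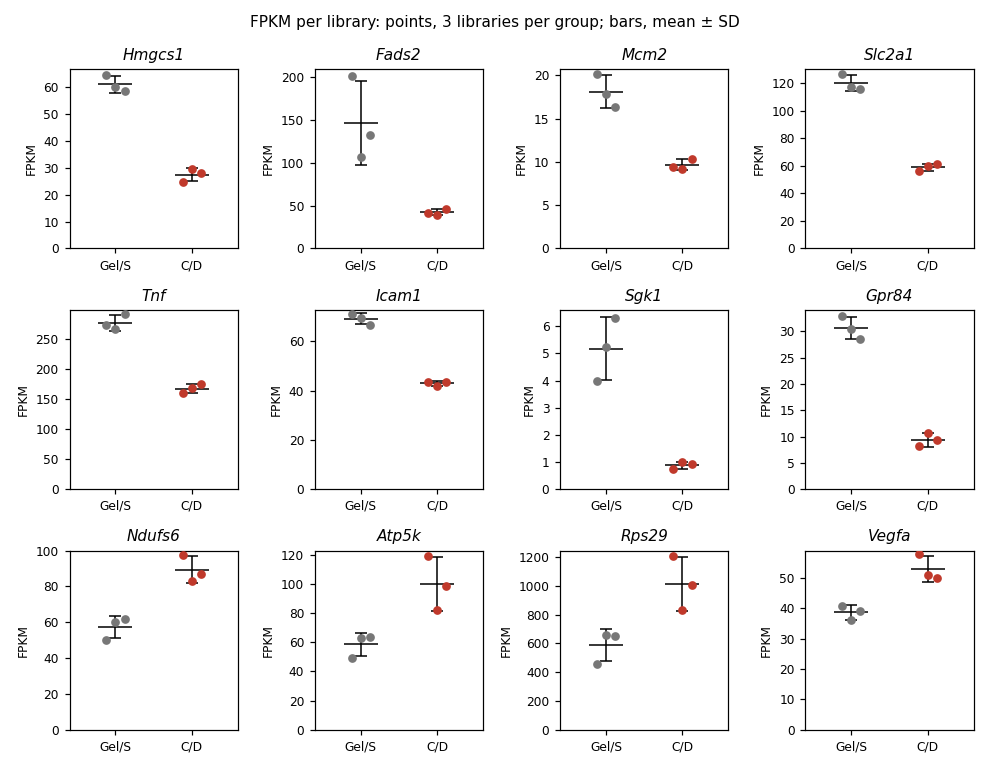
FPKM in each of the 6 libraries for 12 genes named in the text, with points for single libraries and bars for the mean ± SD of Gel/S and C/D (n = 3). The Gel/S and C/D values of Hmgcs1, Slc2a1, Tnf and Icam1 do not overlap, and Hmgcs1 falls from a mean of 61.1 to 27.5 FPKM.

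The steepest falls among well-measured genes included kinases, receptors and lipid enzymes. Sgk1, a serum- and glucocorticoid-induced kinase (chromosome 10, 21882184 to 21999903, GRCm38), fell from 5.17 ± 1.16 to 0.882 ± 0.134 FPKM, a log2 fold change of −2.5 (SE 0.194, edgeR adjusted p = 4.51e-05). Arc, an activity-induced immediate early gene, fell by 2.01 on the log2 scale. Gpr84, a receptor for medium-chain fatty acids (chromosome 15, 103308235 to 103310612), fell from 30.7 ± 2.13 to 9.37 ± 1.28 FPKM (log2 fold change −1.66, SE 0.113, edgeR adjusted p = 4.51e-05). Lipid enzymes among them included Idi1 (log2 fold change −1.93), Fads2 (−1.74) and Aacs (−1.44), and Fads2, a desaturase of polyunsaturated fatty acids, went from 147 ± 48.8 to 42.4 ± 3.71 FPKM. Phlda1 (−1.65), the muscarinic receptor gene Chrm4 (−1.44) and Dcbld2 (−1.40) also fell, as did Sumo2 and Rnu12. Sumo2 had a log2 fold change of −1.69 that shrank to −1.01 without Gel/S 3, and Rnu12, the RNA of the minor spliceosome, lost its call without Gel/S 3, C/D 2 or C/D 3 (highest adjusted p = 0.106).

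Of the 12 steepest rises, 6 were in short or non-coding RNAs. Rn7sk, the small nuclear RNA that holds a transcription elongation factor inactive (chromosome 9, 78175303 to 78175633), rose from 0.572 ± 0.332 to 6.06 ± 2.87 FPKM (log2 fold change 3.38, SE 0.557, edgeR adjusted p = 0.00172). Mir142hg, the host transcript of a microRNA of blood cells (chromosome 11, 87755577 to 87757270), rose from 24.6 ± 3.37 to 62.9 ± 3.87 FPKM (log2 fold change 1.39, SE 0.143, edgeR adjusted p = 0.000127). Mir142b (2.71) lies within it, so they can share reads. Mir703 had a log2 fold change of 1.85. The protein-coding genes were Hap1 (1.68), the troponin gene Tnnt3 (1.41), Cmbl (1.38), the olfactory receptor gene Olfr933 (1.28) and the H2B gene Hist1h2bc (1.27), of which Hap1 and Tnnt3 overlap other genes. Calls of 3 others were fragile. Snord59a (2.83), inside Atp5b, lost its call without any of the 6 libraries in turn (highest adjusted p = 0.140, without C/D 2). Mir339 (1.67), inside another gene, lost it without each library except Gel/S 2 (highest 0.104), and the chemokine gene Ccl5 (1.30) lost it without Gel/S 1, Gel/S 3, C/D 1 or C/D 3, with a log2 fold change of 0.83 and an adjusted p of 0.202 without C/D 1.

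Genes of cholesterol synthesis and uptake fell together. All 24 measured members fell, and 24 fell when adjusted over the list alone, with a median log2 fold change of −0.90 (camera adjusted p = 4.02e-22, and adjusted p = 0.373 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, fell from 61.1 ± 3.18 to 27.5 ± 2.46 FPKM (log2 fold change −1.11, SE 0.0921, edgeR adjusted p = 5.85e-05). Cyp51, the lanosterol demethylase, fell by 1.26 on the log2 scale, Acat2 by 1.14 and Sc5d by 0.95. In the list of cholesterol efflux and lipid loading, 6 of 17 genes fell, none rose and 11 did not pass, with 1 risen and 6 fallen when adjusted over the list alone, and the list itself did not pass camera (median −0.11, adjusted p = 0.114) but was called by fry (adjusted p = 0.0142). Its fallen members include Lpl, the lipoprotein lipase (281 ± 28.1 to 118 ± 12.4 FPKM, log2 fold change −1.22), the stearoyl-CoA desaturases Scd1 (−1.38) and Scd2 (−0.92), and Srebf1 (−0.44), a regulator of fatty acid synthesis.

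Glucose uptake and glycolysis genes fell as well. Of 23 genes of glycolysis and lactate, 15 fell, none rose and 8 did not pass (16 fell when adjusted over the list alone), with a median log2 fold change of −0.45 (camera adjusted p = 4.52e-07, and adjusted p = 0.373 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, fell from 120 ± 5.84 to 58.9 ± 2.70 FPKM (log2 fold change −0.98, SE 0.0862, edgeR adjusted p = 6.29e-05). Hk2, which phosphorylates glucose, fell by 1.08 on the log2 scale, and Slc16a3, a lactate exporter, by 0.98. Gapdh, with many pseudogene copies that can share its reads, was 11.9 ± 2.5 and 11.8 ± 0.439 FPKM (log2 fold change 0.02, adjusted p = 0.916), and its sign turned in several alternatives, among them TPM (−0.08). That level is far below that of Actb (1394 ± 253 FPKM in Gel/S), so how well it tracks Gapdh mRNA is unknown. Among 21 hypoxia (HIF1A) targets, 11 fell, 2 rose and 8 did not pass (15 and 2 when adjusted over the list alone), with a median of −0.38 (camera adjusted p = 0.000291, and adjusted p = 0.373 with an estimated correlation). The hypoxia list shares Slc2a1, Hk2, Pgk1, Ldha, Pdk1, Pfkfb3 and Pfkfb4 with the glycolysis list, so its call is not a separate finding. Bnip3 (−0.73) and Egln1 (−0.54), an oxygen sensor that marks HIF1A for decay, fell, while Vegfa (0.50) and Ddit4 rose. Ddit4 was picked after its value was seen (log2 fold change 0.43), and its call was lost without C/D 2 or C/D 3 (highest adjusted p = 0.0980).

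Other carbon pathways did not pass camera as lists, although fry gave adjusted p = 0.0150 for the TCA cycle and 0.00319 for the pentose phosphate list. In the TCA cycle list, 7 of 24 genes fell and 1 rose, also when adjusted over the list alone (median −0.14, camera adjusted p = 0.0639). Acly, which exports citrate carbon to lipid synthesis, fell by 0.89 on the log2 scale and Acod1, which makes itaconate, by 0.63, while Fh1 rose (0.32). Among 9 genes of the pentose phosphate and NADPH list, 3 fell (Rpia, Pgd, Rpe) and 1 rose (Taldo1), with 5 fallen and 1 risen when adjusted over the list alone (median −0.23, camera adjusted p = 0.0950). Fatty acid oxidation was split, with 4 of 20 genes risen and 4 fallen (6 and 4 when adjusted over the list alone; median −0.01, camera adjusted p = 0.906). Cpt1a, which carries fatty acids into mitochondria, rose (0.39) along with Acaa2, Hadh and Slc25a20, and Acsl4 (−0.64), Hadha (−0.45), Echs1 (−0.36) and Acsl1 fell. Calls were lost with single libraries left out for Fh1, Pgd, Rpe, Taldo1, Acaa2, Hadh, Slc25a20, Acsl1, Cpt1a and Echs1 (highest adjusted p = 0.159, for Rpe without C/D 1), most often without Gel/S 3 or a C/D library.

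DNA replication genes fell in C/D. Of 27 measured genes, 22 fell, none rose and 5 did not pass (24 fell when adjusted over the list alone), with a median log2 fold change of −0.58 (camera adjusted p = 1.75e-14, and adjusted p = 0.373 with an estimated correlation). Mcm2, a subunit of the replicative helicase, fell from 18.1 ± 1.93 to 9.65 ± 0.634 FPKM (log2 fold change −0.86, SE 0.0939, edgeR adjusted p = 0.000174). Uhrf1, which maintains DNA methylation at replication forks, fell by 1.11 on the log2 scale, Mcm4 by 0.93 and Mcm5 by 0.90. Of 27 mitosis genes, 13 fell, none rose and 14 did not pass (14 fell and 1 rose when adjusted over the list alone), with a median of −0.27 (camera adjusted p = 0.000472, and adjusted p = 0.410 with an estimated correlation). Prc1, a bundler of spindle microtubules, fell by 0.84 on the log2 scale and the kinesin Kif20a by 0.48. The mitosis count was smaller with single libraries left out, 2 without C/D 1, 2 without C/D 2, 6 without C/D 3 and 6 without Gel/S 3, and was 10 with limma on log2(FPKM + 1), 8 with limma on TPM and 5 with limma after quantile normalization. Of 15 p53 targets and arrest genes, 2 rose (Trp53inp1, 0.93; Btg2, 0.44) and 2 fell (Gadd45b, −0.76; Gadd45a, −0.73), also when adjusted over the list alone (median −0.02, camera adjusted p = 0.801). Btg2 lost its call without Gel/S 3, C/D 2 or C/D 3 (highest 0.0916), and Gadd45a without Gel/S 3 or C/D 2 (highest 0.0768).

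Among 5 measured histone genes, 3 rose and 2 did not pass, also when adjusted over the list alone (median log2 fold change 0.92, camera adjusted p = 0.0324, and adjusted p = 0.373 with an estimated correlation). Hist1h1c, a linker histone gene, rose from 49.4 ± 2.76 to 105 ± 13.9 FPKM (log2 fold change 1.13), with Hist1h2bc (1.27) and Hist2h4 (0.92), which lost its call without C/D 1 or C/D 2 (highest adjusted p = 0.0994). The list's own call was lost without Gel/S 1 (adjusted p = 0.0824), within a range over its alternatives of 0.00792 to 0.650, and its mean turned to −0.19 without a filter on low levels, and limma with sample weights gave 3 risen and 2 fallen with a median of 0.51 (0.58 with limma on log2(FPKM + 1)). Most canonical histone mRNAs lack poly(A) tails, and Rn7sk, which also lacks one, rose in the same libraries. Other small RNAs did not follow it as a group, with 0 risen and 4 fallen of 55 small nuclear RNA genes and 3 risen of 105 small nucleolar RNA genes. Whether the missing tails bear on the histone rise was not tested.

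Nuclear genes for the respiratory chain were higher as lists in C/D by camera, while fry did not call them (adjusted p = 0.0602 for complex I, 0.0963 for complexes II to IV and 0.0818 for ATP synthase). In complex I, the entry point of electrons from NADH, 21 of 36 genes rose, none fell and 15 did not pass (24 rose when adjusted over the list alone), with a median log2 fold change of 0.39 (camera adjusted p = 1.15e-08, and adjusted p = 0.423 with an estimated correlation). Ndufs6 rose from 57.2 ± 6.17 to 89.2 ± 7.57 FPKM (log2 fold change 0.68, SE 0.107, edgeR adjusted p = 0.00133), and Ndufa13 (0.66), Ndufa1 (0.65) and Ndufb3 (0.64) rose as well. Of 28 genes of complexes II to IV and cytochrome c, 10 rose and none fell, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.00343, and adjusted p = 0.459 with an estimated correlation), among them Cox5b (0.59) and Cox7c (0.58). That median was 0.17 without Gel/S 1, 0.15 on TPM and 0.15 after the length and GC correction. Of 18 ATP synthase genes, 9 rose, 1 fell and 8 did not pass, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.000291, and adjusted p = 0.437 with an estimated correlation). Atp5k rose from 58.6 ± 8.07 to 99.9 ± 18.8 FPKM (0.81) and Atp5mpl rose by 0.59 on the log2 scale, while the catalytic-core gene Atp5a1 fell (−0.42), a call lost without C/D 2 or C/D 3 (highest 0.0608). The counts risen depended on the libraries and on the test: complex I gave 13 without C/D 1, 12 without C/D 3, 12 on TPM, 13 with limma on log2(FPKM + 1) and 11 without its trend. Complexes II to IV gave 6 without C/D 1, and ATP synthase 4 without C/D 1 and 5 with limma without trend, with a median of 0.20 on TPM. The mitochondrial share of the counts was higher in the same C/D libraries (9.84 ± 0.606% against 7.34 ± 1.72%), though Gel/S 2 (9.02%) came close to C/D 1 (9.17%).

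Transcripts of the mitochondrial genome were higher as a list by camera, though not by fry (adjusted p = 0.110), with 2 of 13 mRNAs risen and none fallen, and none risen when adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 0.0264, and adjusted p = 0.495 with an estimated correlation). The risen ones were mt-Co3 (0.64, adjusted p = 0.0265) and mt-Nd5 (0.47, adjusted p = 0.0476). The list's median was 0.26 without Gel/S 1, 0.14 after quantile normalization and 0.18 after the length and GC correction. Without Gel/S 3, 0 rose (edgeR), and without Gel/S 2, 11 rose. The call of mt-Co3 was lost without Gel/S 3 or C/D 1 (log2 fold change 0.42 without C/D 1), and that of mt-Nd5 without Gel/S 3 or any C/D library, with a log2 fold change of 0.30 without Gel/S 1. The list's call was lost without Gel/S 1 (adjusted p = 0.0880, range over its alternatives 0.00131 to 0.213).

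Genes that build, move or clear mitochondria did not pass camera as lists, although fry called the list of mitochondrial dynamics. Of 32 genes of mitochondrial dynamics, biogenesis and transfer, 4 fell (Timm23, Tnfaip2, Nrf1, Vdac1) and 2 rose (Mief2, Ppargc1b), also when adjusted over the list alone (median −0.11, camera adjusted p = 0.0866). Timm23, of the inner-membrane import channel, fell from 23.4 ± 0.970 to 16.5 ± 0.294 FPKM (log2 fold change −0.47), and Tfam, which packages mitochondrial DNA, had a log2 fold change of −0.20 (adjusted p = 0.133). Ppargc1a had no counts in any library. Of 19 mitophagy and autophagy genes, 3 fell (Bnip3, Gabarap, Bnip3l) and 2 rose (Ulk1, 0.56; Map1lc3b), also when adjusted over the list alone (median −0.06, camera adjusted p = 0.395). Of 11 genes of the mitochondrial unfolded protein response, 4 fell (Hspd1, Hspa9, Lonp1, Dnaja3) and 1 rose (Hspe1), also when adjusted over the list alone (median −0.13, camera adjusted p = 0.210). The chaperonin partners moved apart, Hspd1 by −0.50 and Hspe1 by 0.50, although the genes lie side by side and overlap. Calls lost with single libraries left out were those of Tnfaip2, Nrf1, Vdac1, Mief2, Ppargc1b, Bnip3l, Map1lc3b, Hspa9, Lonp1 and Dnaja3 (highest adjusted p = 0.146, for Vdac1 without C/D 2).

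Ribosomal protein genes were higher as lists by camera, though most members did not pass and fry did not call the lists (adjusted p = 0.129 for cytosolic and 0.242 for mitochondrial ones). Of 53 cytosolic ribosomal protein genes, 18 rose, 1 fell (Rps2, −0.41) and 34 did not pass, with 23 risen and 1 fallen when adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 9.49e-06, and adjusted p = 0.510 with an estimated correlation). Rps29 rose from 589 ± 112 to 1016 ± 188 FPKM (0.83, SE 0.162, edgeR adjusted p = 0.00404), and Rpl26 (1.24), Rpl22 (0.65) and Rps28 (0.61) rose as well. These genes have many processed pseudogenes that can share their reads. The median was 0.18 without Gel/S 1, 0.15 on TPM (9 risen) and 0.14 after quantile normalization (11 risen), and 8 rose with limma on log2(FPKM + 1). The count risen was 30 without Gel/S 2, 11 without Gel/S 3, 7 without C/D 1, 11 without C/D 2 and 9 without C/D 3, and Rps2 lost its call without Gel/S 3, C/D 1 or C/D 3. Of 44 mitochondrial ribosomal protein genes, 7 rose, 1 fell and 36 did not pass, with 3 risen and 1 fallen when adjusted over the list alone (median 0.16, camera adjusted p = 0.0144, and adjusted p = 0.630 with an estimated correlation). Mrps16 (0.51) and Mrpl22 (0.50) rose and Mrpl3 fell (−0.40), the latter not called without C/D 2 (0.0520). On TPM 2 rose and 3 fell (median 0.03), with limma on log2(FPKM + 1) 2 rose and 2 fell, and the list's call was lost on TPM and after the length and GC correction (camera adjusted p = 0.0990, median 0.09). That list was not called without Gel/S 1 (median 0.08, adjusted p = 0.156, range over its alternatives 0.000465 to 0.197), and its count risen was 3 without Gel/S 1, 3 without Gel/S 3, 2 without C/D 1, 3 without C/D 2, 2 without C/D 3 and 15 without Gel/S 2.

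Targets of NF-kB, the transcription factor of inflammatory activation, fell. Of 23 genes, 15 fell, none rose and 8 did not pass (15 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of −0.33 (camera adjusted p = 6.19e-06, and adjusted p = 0.373 with an estimated correlation). Icam1, a leukocyte adhesion molecule, fell from 69.1 ± 2.24 to 43.0 ± 1.02 FPKM (log2 fold change −0.64, SE 0.0819, edgeR adjusted p = 0.000431). Tnfaip3, a brake on NF-kB itself, fell by 0.64 on the log2 scale, Traf1 by 0.65 and the subunit gene Nfkb1 by 0.51. The count fallen was 9 without Gel/S 3 and 7 without C/D 2. Of 13 chemokine and receptor genes, 7 fell and 1 rose (Ccl5), also when adjusted over the list alone (median −0.35, camera adjusted p = 0.0354, and adjusted p = 0.373 with an estimated correlation). The chemokine list shares Ccl3, Ccl4 and Cxcl2 with the NF-kB targets. Ccl9 fell from 234 ± 30.1 to 122 ± 9.94 FPKM (−0.90), the neutrophil attractant Cxcl2 by 1.14 on the log2 scale and Cx3cr1 by 0.47. The count fallen was 4 without Gel/S 3 and 4 without C/D 2, and the list's adjusted p ranged from 0.00555 to 0.161 over its alternatives.

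Interferon-stimulated genes were higher as a list, with 7 of 24 risen and none fallen, also when adjusted over the list alone (median log2 fold change 0.15, camera adjusted p = 0.0159, and adjusted p = 0.373 with an estimated correlation). Isg20, an antiviral exonuclease, rose by a log2 fold change of 1.04, Rtp4 by 0.92 (3.84 ± 0.596 to 7.07 ± 0.785 FPKM), Oas2 by 0.43 and Bst2, which tethers budding viruses, by 0.34. The median was 0.02 on TPM, with 3 risen, and 0.09 with limma on log2(FPKM + 1). Only 3 rose without Gel/S 3, C/D 1 or C/D 3 and 4 without C/D 2, Bst2 was not called without Gel/S 3, C/D 2 or C/D 3, and Oas2 not without C/D 1. Of 14 inflammasome and pyroptosis genes, 7 rose and 2 fell, also when adjusted over the list alone, and the list did not pass camera (median 0.31, adjusted p = 0.0905) but was called by fry. Txnip rose from 617 ± 20.7 to 931 ± 28.2 FPKM (0.63), Casp1, the protease that activates interleukin-1 family cytokines, rose by 0.53 and Naip5 by 0.53, whereas the sensor gene Nlrp3 fell (−0.40) with Naip2 (−0.41, not called without Gel/S 1 or any C/D library).

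Markers of macrophage polarisation were split. Of 13 measured markers of the pro-inflammatory (M1) state, 3 rose (Socs3, Ccl5, Il18), 1 fell (Tnf) and 9 did not pass, with 5 risen and 2 fallen when adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 0.411). Tnf had a log2 fold change of −0.68 (SE 0.0887, edgeR adjusted p = 0.000456). Socs3 (0.35) lost its call without C/D 2 or C/D 3 and Il18 (0.33) without each library except Gel/S 2 (highest 0.129). Nos2, the inducible nitric oxide synthase, had a log2 fold change of 0.49 (adjusted p = 0.154) and Il1b of −0.14 (adjusted p = 0.694). Of 15 markers of the alternative (M2) state, 6 fell and 2 rose (Clec10a, 0.40; Stab1, 0.45), with 7 and 5 when adjusted over the list alone (median −0.24, camera adjusted p = 0.315). Tgfb1, a cytokine of repair, fell from 65.6 ± 3.89 to 46.4 ± 1.49 FPKM (−0.46, edgeR adjusted p = 0.00368), and the transcription factor genes Klf4 (−1.04), Egr2 (−0.76) and Myc (−0.68) fell, Myc not without C/D 3 (0.0562). Clec10a was not called without Gel/S 3, C/D 1 or C/D 2, nor Stab1 without any library but Gel/S 2. Several classic markers lay below the level tested, with summed counts in Gel/S and C/D of 62 and 72 for Cd86, 1 and 0 for Il6, 26 and 36 for Arg1, 107 and 105 for Mrc1, 1 and 1 for Cd163 and 1 and 5 for Il10.

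Stress genes fell more often than they rose. Of 23 genes of ER stress and the integrated stress response, 12 fell, 1 rose and 10 did not pass (14 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of −0.33 (camera adjusted p = 0.000127, and adjusted p = 0.373 with an estimated correlation). Sdf2l1, an ER chaperone partner, fell by 0.72 on the log2 scale, the serine synthesis gene Psat1 and Ppp1r15a each by 0.69, and Ern1, the ER stress sensor IRE1, rose (0.74). Of 11 heat shock genes, 4 fell (Dnajb1, −0.55; Hsp90aa1, −0.55; Hspd1; Hsph1, −0.42) and 1 rose (Hspe1), also when adjusted over the list alone (median −0.17, camera adjusted p = 0.0653, fry adjusted p = 0.00719). Of 21 immediate early and mechanosensitive genes, 10 fell, 2 rose (Nr4a1, 0.91; Fosl2, 0.27) and 9 did not pass (11 and 3 when adjusted over the list alone), with a median of −0.33 (camera adjusted p = 0.00651, and adjusted p = 0.410 with an estimated correlation). Egr1 fell from 48.6 ± 5.61 to 29.1 ± 4.93 FPKM (−0.70), Klf4 by 1.04 on the log2 scale and the integrin gene Itga5 by 0.52. The count fallen was 6 without C/D 2 and 6 with limma on log2(FPKM + 1), and Fosl2 was not called without Gel/S 3 or any C/D library (highest 0.0923).

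Antioxidant genes moved both ways. Of 19 NRF2 targets, 6 rose and 2 fell (Txnrd1, −0.63; Gsr, −0.56), with 7 and 3 when adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 0.191). Hmox1, which degrades heme, rose from 123 ± 14.6 to 196 ± 34.3 FPKM (0.71, edgeR adjusted p = 0.00343), with Blvrb (0.67) and Gclm (0.53). Of 19 other redox enzymes, 4 rose (Glrx2, 0.41; Sod1, 0.52; Cat, 0.32; Prdx2, 0.31) and 2 fell (Cybb, −0.70; Prdx3, −0.27), also when adjusted over the list alone (median 0.00343, camera adjusted p = 0.606). Cybb is the catalytic subunit of the phagocyte oxidase. Of 13 genes of iron handling and metallothioneins, 2 rose (Hmox1; the iron exporter gene Slc40a1, 0.45) and 1 fell (Aco1, −0.62), also when adjusted over the list alone (median 0.06, camera adjusted p = 0.742). Sod1 was not called without C/D 1, Cat and Prdx3 not without Gel/S 3 or any C/D library, and Prdx2 not without any library but Gel/S 2 (highest adjusted p = 0.154, for Prdx3 without C/D 1).

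Secreted factors that act on bone and vessels went both ways. Of 11 measured osteogenic and angiogenic factors, 3 rose (Vegfa; Angptl4, 0.60; Igf1, 0.35) and 3 fell (Pdgfb; Sema4d, −1.0; Tgfb1), also when adjusted over the list alone. The list's median was 0.05, its mean −0.09 and its test pointed lower without passing (camera adjusted p = 0.742). Pdgfb, a growth factor for pericytes and mesenchymal cells, fell from 26.3 ± 1.08 to 11.4 ± 1.02 FPKM (−1.16, SE 0.0894, edgeR adjusted p = 4.51e-05), and Vegfa rose with a log2 fold change of 0.50 (SE 0.0925, edgeR adjusted p = 0.00323). Osm, an osteogenic cytokine of macrophages, had a log2 fold change of 0.16 (adjusted p = 0.50), and Bmp2 had summed counts of 2 in Gel/S and 1 in C/D. Angptl4 was not called without C/D 2 (0.0677), nor Igf1 without Gel/S 3, C/D 2 or C/D 3 (highest 0.0941).

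Osteoclast genes were likewise split, with 3 of 16 risen (Atp6v0d2, Car2, Acp5) and 5 fallen (Dcstamp, Cd44, Csf1r, Myo1d, Ostm1), and 4 and 5 when adjusted over the list alone (median log2 fold change −0.01, camera adjusted p = 0.712). Acp5, the tartrate-resistant acid phosphatase, rose from 14.8 ± 1.08 to 20.8 ± 3.08 FPKM (0.53, edgeR adjusted p = 0.00818), Atp6v0d2 by 0.83 and Car2 by 0.70. Dcstamp, needed for cell fusion, fell from 29.9 ± 0.683 to 14.9 ± 0.973 FPKM (−0.96). Nfatc1, the master regulator of osteoclast formation, had a log2 fold change of 0.06 (adjusted p = 0.666), and −0.07 on TPM. Of 33 lysosome genes, 7 fell, 3 rose (Mcoln1, Ctsl, Ctss) and 23 did not pass, also when adjusted over the list alone (median −0.14, camera adjusted p = 0.0482, and adjusted p = 0.459 with an estimated correlation). The protease gene Ctsb fell from 747 ± 58.8 to 518 ± 6.19 FPKM (−0.48) and Gusb by 0.63 on the log2 scale. The count fallen was 12 without Gel/S 2, 4 without Gel/S 3, 4 without C/D 1, 3 without C/D 2, 3 without C/D 3, 5 with limma on log2(FPKM + 1), 2 with limma after quantile normalization and 19 with limma and sample weights, and the list's adjusted p ranged from 0.000649 to 0.161 over its alternatives, while its median was −0.27 on TPM and −0.22 without Gel/S 2. Mcoln1 was not called without Gel/S 3 or C/D 2, Ctsl and Ctss not without Gel/S 3 or any C/D library, and Ostm1 not without any library but Gel/S 2. Of 8 matrix and adhesion genes, 2 fell (Cd44, −0.90; Itgax, −0.71) and none rose, also when adjusted over the list alone (median −0.28, camera adjusted p = 0.0720, fry adjusted p = 0.0120).

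**Figure D2:**
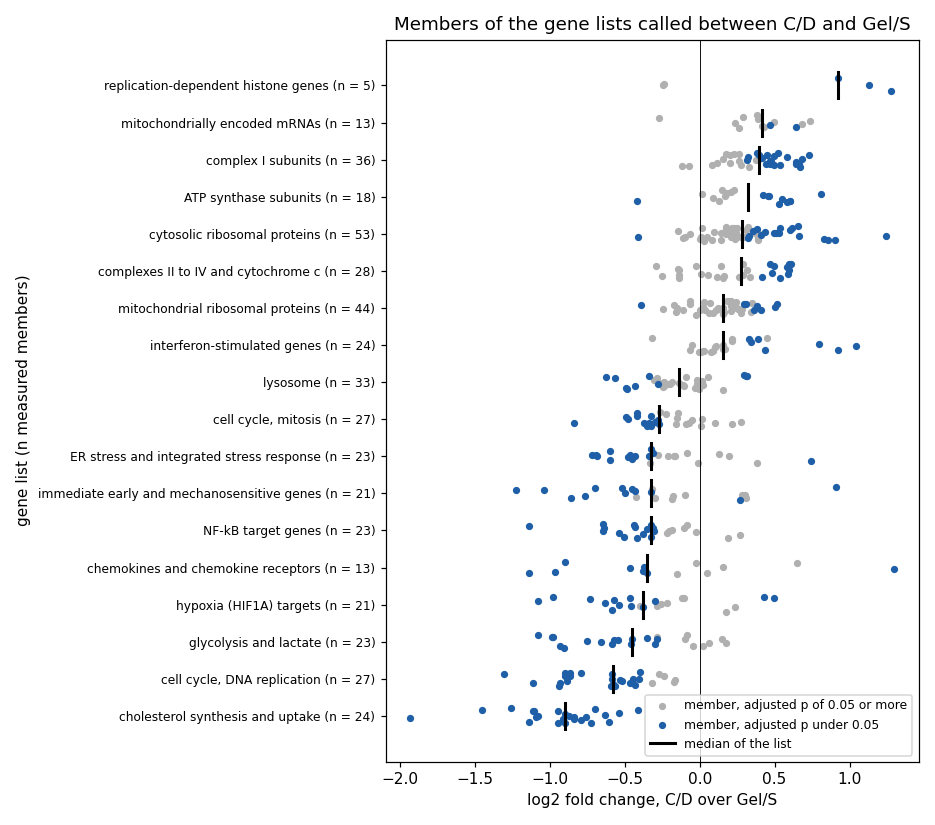
Log2 fold change (C/D over Gel/S) of each measured member of the 18 lists that passed the camera test, with blue points for genes with an adjusted p under 0.05, grey points for the others and a black bar at each list's median. All 24 cholesterol synthesis genes lie below 0, and the medians of complex I, ATP synthase and cytosolic ribosomal protein genes lie above 0.

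Markers of cell identity were mostly those of a macrophage line, the main exception being Ighm of the lymphocyte list, at a mean of 170 FPKM. Of 22 macrophage identity genes, 5 fell (Csf1r, C1qa, C1qb, Laptm5, Fcgr2b), 1 rose (Ctss) and 16 did not pass, with 7 and 3 when adjusted over the list alone. The list's median log2 fold change was 0.02, its mean −0.15 and its test pointed lower without passing (camera adjusted p = 0.588). Csf1r, the receptor for the macrophage growth factor, fell from 550 ± 58.4 to 382 ± 12.9 FPKM (−0.48), and C1qa by 1.52 on the log2 scale at a low level. The summed FPKM of these genes, led by Lyz2 at a mean of 9110, was 17286 ± 46.6 in Gel/S and 15102 ± 38.8 in C/D (exact p = 0.1). None of the stromal and osteoblast markers (summed FPKM 2.02 and 2.10) or the endothelial and epithelial markers (0.675 and 0.726) reached the level tested. The dendritic cell list had 3 measured genes, of which 2 fell (Itgax; Siglech, −0.80), the neutrophil list 1, which fell (Csf3r, −0.37), and the lymphocyte list 1, which rose (Ighm, 143 ± 14.2 to 197 ± 29.6 FPKM, 0.51), the same counts as when adjusted over the list alone. Csf3r was not called without C/D 2 (0.0548), Ighm without C/D 1 (0.0511), C1qb without C/D 1 or C/D 3, Laptm5 and Ctss without Gel/S 3 or any C/D library, and Fcgr2b without any library but Gel/S 1. Laptm5 had a log2 fold change of −0.30 without Gel/S 1. Actb, a common reference gene, had a log2 fold change of −0.12 (adjusted p = 0.539).

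Non-coding genes moved up more often than down. Of 9953 protein-coding genes, 1246 rose and 1562 fell, while of 1755 genes of other biotypes 286 rose and 69 fell. Long intergenic non-coding RNA genes gave 67 risen and 4 fallen of 221, with a median log2 fold change of 0.40, and antisense genes 35 and 4 of 188. Long non-coding RNA genes of bidirectional promoters gave 14 and 0 of 28. Among small RNAs, 6 microRNA genes and 3 of 105 small nucleolar RNA genes rose, and 4 of 55 small nuclear RNA genes fell. Processed pseudogenes gave 67 risen and 50 fallen of 668. The medians of long intergenic and antisense genes kept their sign in every scaling tried, with lowest values of 0.21 and 0.15. Strand was not stated, so reads of antisense genes and of their partners cannot be told apart here.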

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

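The genes described first and the test on long non-coding RNAs were chosen after their values were seen, and the tests on short genes and on nuclear-retained RNAs before. Outside the genes tested, 12150 genes had a count but a mean FPKM under 1, and an edgeR fit without the filter called 369 of them, 311 higher and 58 lower in C/D. Of these, 9 had no count in any Gel/S library and a count in every C/D library, and 8 showed the mirror image. Oas1d, a member of the interferon-induced oligoadenylate synthetase family (chromosome 5, 120914536 to 120921652, GRCm38), stood out with 32 counts in C/D, 15, 4 and 13 in the 3 libraries (adjusted p = 1.02e-05 in the unfiltered edgeR fit, higher in 3 of 3), at least 11.8-fold higher against a floor of 3 counts over the group. Its neighbour and paralog Oas1a, whose reads it can share, was 15.2 ± 2.43 FPKM in Gel/S and 14.1 ± 0.671 in C/D (log2 fold change −0.07, edgeR adjusted p = 0.721). The others had few counts in C/D: Gm17082 16, AC132444.1 13, A230005M16Rik 12, Gm3417 11, and Gm10748, Gm13274, Gm47400 and Mir466i 10 each, with unfiltered adjusted p-values by edgeR of 0.00608 to 0.0497.

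Non-coding RNAs rose more often than they fell in C/D, as given above, though few small RNAs passed, with 4 of 55 small nuclear RNA genes fallen and 3 of 105 small nucleolar RNA genes risen. For the long ones, length alone is argued against, since genes of other biotypes of at least 4000 bases gave 36 risen and 1 fallen of 83 (median log2 fold change 0.37), whereas 5437 coding genes of that length had a median of −0.05. Among genes under 500 bases, though, 47 coding genes had a median of 0.50 and 773 others of 0.36, a ratio of 1.38, so a dependence on length could account for the short ones. More nuclear RNA in the C/D libraries is the other candidate explanation that stays open. The 4 long RNAs chosen in advance as nuclear-retained had a median of 0.37 (percentile 97.7 of matched lists), though that label is doubtful for Gas5. Malat1 rose from 265 ± 10.03 to 400 ± 12.7 FPKM and Neat1 from 77.6 ± 9.22 to 108 ± 11.7. The call of Neat1 was lost without C/D 2 (edgeR adjusted p = 0.0677). Gas5 (0.04) and Mir17hg (0.22) did not pass, so the rise rests on Malat1 and Neat1. A response of the cells to the C/D culture also stays open, untested.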

How the results depend on the processing

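The settings length and GC correction, filterByExpr and nuclear protein-coding genes were chosen after the data were seen, and limma on log2(FPKM + 1) became an alternative when counts were found. The others were chosen before. At the base setting, 1532 genes rose, 1631 fell, 8 lists were higher and 10 lower. No gene called both there and in an alternative changed sign. At least 1 count moved by over 1.5 times in the following settings, and the cause was not tested unless stated: limma on log2(FPKM + 1) with 1020 risen and 1471 fallen, 1016 and 1486 with a pseudocount of 0.5, 1008 and 1492 with 0.1, 1012 and 1354 without trend, 633 and 1510 on TPM, and 2940 and 3748 with sample weights. A Welch test, which borrows no spread across genes, gave 0 and 0 (edgeR has 4800 genes at an unadjusted p under 0.05, limma and DESeq2 the counts given here), and 5 lists higher and 9 lower. By construction, a fold threshold lowers the counts, to 202 and 71 with unadjusted p and 153 and 61 with adjusted p. DESeq2 gave 1538 and 1659, and 1061 and 1640 without a filter. The length and GC correction left 5 lists higher and 9 lower, and 1661 and 1943 genes. Without any filter 7 lists were higher and 15 lower. With an estimated correlation, camera gave 0 higher and 0 lower lists. Leaving out 1 library gave 887 to 1989 risen and 876 to 2089 fallen genes, and 5 to 8 lists higher and 8 to 11 lower, with fewer samples in each fit. Of 158 named genes called, 130 to 157 kept their call there. Of the called lists, NF-kB targets, complex I, ATP synthase, glycolysis, hypoxia targets, ER stress, cholesterol synthesis, replication, mitosis and cytosolic ribosomal proteins passed in 22 of 22 alternatives other than the estimated correlation. Losses came to 10 for chemokines, 8 for lysosome genes, 6 for histones, 4 each for mitochondrial mRNAs and mitochondrial ribosomal proteins, 2 each for interferon-stimulated and immediate early genes and 1 for complexes II to IV.

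For a list's own value, 3 summaries were tried, the direction of the camera test, the median and the mean log2 fold change, and the mean was chosen after the sign changes under each were known. Of 849 list values over the alternatives, 27 changed sign by the mean, 57 by the median and 19 by the camera direction, so the mean is not the strictest choice. By the median, macrophage identity genes (−0.02) and iron handling and metallothioneins (−0.07) also turn negative with limma on log2(FPKM + 1). Among lists called by camera and genes called by edgeR, only the histone list changed sign by the mean, to −0.19 without a filter (adjusted p = 0.650). Also without a filter, Gapdh was −0.0214, M1 markers −0.0173, M2 markers 0.12, other redox enzymes −0.0198, iron handling −0.0322, osteogenic factors 0.15, osteoclast genes 0.15, p53 targets 0.15 and matrix genes 0.25. Other redox enzymes were −0.0121 with limma on log2(FPKM + 1), without trend and by the Welch test, −0.0114 and −0.0106 with pseudocounts of 0.5 and 0.1, −0.10 on TPM, −0.0327 with sample weights, −0.00186 with filterByExpr and −0.0271 to 0.0799 with 1 library left out. Gapdh was −0.0831 on TPM, −0.10 with sample weights, −0.0172 in DESeq2 without a filter, −0.00416 with filterByExpr and −0.14 to 0.16 with 1 library left out, and Actb −0.25 to 0.0245. For the list fatty acid oxidation, the mean was 0.0242 at a filter of 5 FPKM, 0.00874 after quantile normalization, 0.00900 with nuclear protein-coding genes and −0.0290 to 0.0167 with 1 library left out. At 5 FPKM, osteoclast genes were 0.00571 and p53 targets 0.00178. On TPM, Nfatc1 was −0.0725 and iron handling −0.0755, and osteogenic factors were 0.00647 with filterByExpr.

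No sign of pairing by replicate number was seen, since same-numbered libraries deviated with correlations of −0.0568, −0.0589 and 0.0454, and not every library correlated best with its own number. These values cannot exclude a shared culture or day, which the labels do not state. With the replicate block, 1242 genes rose and 1302 fell, and 8 lists were higher and 11 lower. At this depth and with 3 libraries a group, a 1.3-fold change was called in 23.3% of simulated genes. The simulation changed far fewer genes (150 at each fold over 3 datasets, beside 34524 unchanged) than the 3163 called here. That makes its adjusted threshold stricter, so the share missed in these data is not known from it.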

Other observations

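The lists and factor families described here were chosen after the main results were seen, and so was the liver X receptor test, while the other tests were chosen before their results were seen. Genes of the actin cytoskeleton and its adhesions fell in C/D, with 17 of 26 fallen, none risen and a median log2 fold change of −0.41 (camera adjusted p = 3.12e-06, and adjusted p = 0.166 with an estimated correlation). Flna, which crosslinks actin filaments, fell from 41.6 ± 7.92 to 24.0 ± 1.00 FPKM (log2 fold change −0.75), Actg1, a cytoplasmic actin, from 213 ± 25.7 to 127 ± 5.39 (−0.70), and Tln1, which couples integrins to actin, by 0.58 on the log2 scale. Vcl, vinculin of focal adhesions, fell by 1.23, and by 0.77 without Gel/S 1. Srf, a transcription factor that drives actin genes, fell from 19.2 ± 0.892 to 12.2 ± 0.407 FPKM (−0.62). Ribosome biogenesis genes were lower as a list, with 8 of 25 fallen (median −0.21, camera adjusted p = 0.000651, and adjusted p = 0.166 with an estimated correlation), among them Utp20 (−0.64). So were cytosolic tRNA synthetases, with 7 of 20 fallen (median −0.18, camera adjusted p = 0.000777, and adjusted p = 0.166 with an estimated correlation), among them Wars (−0.45) and Aars (−0.42). The tRNA synthetase median lay within the range of matched random lists (percentile 21.9), and 4 fell without Gel/S 3, C/D 2 or C/D 3. Ribosome biogenesis gave 4 fallen without C/D 1 and 5 without C/D 2. No call was made for 28 proteasome subunits (1 rose, 3 fell, median 0.04, camera adjusted p = 0.677), 15 V-ATPase subunits (none rose, 2 fell, median −0.11, 0.236) or 20 Toll-like receptors and adaptors (2 rose, 3 fell, median −0.08, 0.257). Tlr2, a receptor for bacterial lipoproteins, fell by 0.54 on the log2 scale and Tlr4, the lipopolysaccharide receptor, rose (0.36), a call lost without Gel/S 3, C/D 2 or C/D 3 (highest edgeR adjusted p = 0.111).

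Of 691 transcription factor genes tested, 135 rose and 72 fell (median log2 fold change 0.10, camera adjusted p = 0.0926). Of 23 families tested, C2H2 zinc fingers were higher, with 79 of 310 risen and 13 fallen (median 0.19, camera adjusted p = 3.80e-05, and adjusted p = 0.187 with an estimated correlation), and E2F genes lower, with 6 of 10 fallen (median −0.41, camera adjusted p = 0.0340, and adjusted p = 0.306 with an estimated correlation). The zinc finger count risen was 42 without Gel/S 3, 49 without C/D 1, 46 without C/D 2 and 47 without C/D 3, and their median was 0.05 on TPM. The E2F count was 3 without C/D 1 or C/D 3. Klf10, an early gene induced by TGF-beta, rose from 11.0 ± 0.678 to 25.2 ± 2.79 FPKM (1.24, edgeR adjusted p = 5.85e-05). E2f1, which drives S phase, fell by 0.59 on the log2 scale. Among 9 Rel-homology genes, the NF-kB subunits Rela (−0.56), Relb (−0.54), Nfkb1 (−0.51) and Nfkb2 (−0.42) fell with Nfatc3, whose call was lost without any library but Gel/S 2, and Nfat5, a regulator of the response to osmotic stress, rose (0.55), although the family did not pass (median −0.34, camera adjusted p = 0.161).

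Complex I, ATP synthase and cytosolic ribosomal protein genes were higher as lists in C/D by camera, with adjusted p = 0.423, 0.437 and 0.510 with an estimated correlation. Against a trend with gene length and GC content as the whole cause, 3 of 3 lists lay above the central 95% of matched random lists (percentiles 100, 99.97 and 100). They kept medians of 0.27, 0.25 and 0.21 after correction for it. Short coding genes rose as a class, however, with 75 risen and 6 fallen of 235 between 500 and 1000 bases (median 0.31). The matched lists had medians of only 0.06, −0.02 and −0.04. How closely they matched the members in length was not checked, so length is not excluded. Gel/S 1, the library farthest out, is not the sole source, since the medians of complex I and ATP synthase were 0.29 and 0.23 without it, though the cytosolic ribosomal median fell from 0.28 to 0.18. Reads shared with pseudogenes stay open, untested, as does a change in the cells with the C/D culture.

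Cholesterol synthesis and DNA replication genes were lower in C/D (adjusted p = 0.373 for each with an estimated correlation), and 2 of 2 lists lay below the 2.5th percentile of lists matched on length, GC content and expression. Without Gel/S 1 the cholesterol median was −0.88, so that library is not the sole source. A fall that reaches beyond sterol genes was tested on 8 fatty acid synthesis genes not looked at before, of which 7 fell, with a median of −0.48 (percentile 0 of matched lists, camera adjusted p = 8.04e-05, and adjusted p = 0.235 with an estimated correlation), Fasn going from 41.5 ± 4.55 to 20.8 ± 0.184 FPKM, which is consistent with a wider fall of lipid synthesis. Sterol loading of the cells stays open, since 5 liver X receptor targets had a median of 0.18, between the bounds set for it. Over the alternatives this median ran from 0.01 to 0.23, past the lower bound in some and the upper in others. None of the targets rose, Lpcat3 fell (−0.46) and the camera test pointed lower (adjusted p = 0.937). Srebf1, Scd1 and Lpl, given above as fallen, were not among the genes of this test. The lower replication mRNA may reflect slower growth in C/D, which was not tested.

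Falls of Egr1, Etv5 and Phlda1 raised the hypothesis of lower ERK pathway output, tested on 8 feedback genes not looked at before, though Fosl1 was in the immediate early list. Their median was −0.10 (percentile 23.7 of matched lists, range over the alternatives −0.30 to −0.01), with Spred1 and Spred2 fallen and none risen, and the call of Spred1 was lost without Gel/S 3, C/D 1 or C/D 2 (highest edgeR adjusted p = 0.0731). The median lies at the bound set against the hypothesis and past it by less than the spread of the members, a margin that was required only after the value was seen, so the test leaves it undecided and gives it no backing.

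The 10 ways to split the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 3163 genes and the highest other 0 by edgeR, so 1 of 10 gave as many. For gene lists, the real split gave 18 and the highest other 13, again 1 of 10. Every other split also gave lists by camera with its preset correlation, from 2 to 13, though 0 genes passed. Each of these splits sets 2 libraries of 1 group and 1 of the other against the rest, so part of the real difference remains in them. They cannot tell that remainder from lists that camera calls too readily.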
